A study of Mus musculus with 5 samples.

How the data were processed

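RNA-seq was measured on dendritic cells sorted from bone marrow cultures of Etv3+/+ and Etv3-/- mice. Per the labels' protocols, marrow cells were cultured for 6 days with GM-CSF at 20 ng/ml and IL-4 at 5 ng/ml, cytokines that drive marrow progenitors to dendritic cells. Live single cells positive for CD11c, intermediate for CD11b, high for MHC class II and negative for CD115 were sorted to a purity above 95%. RNA of up to 60000 sorted cells was extracted with a column kit and made into cDNA libraries with a low-input SMART-Seq kit, per the labels' protocols. PCR copies cannot be told from separate molecules in such libraries.

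The authors deposited a table of normalized gene counts for 27678 gene symbols and 5 libraries, a signal in which each read count is divided by a factor for its library. Per the submitters' processing notes, the tools were Trimmomatic 0.36, STAR 2.7.3a, featureCounts, Subread 1.6.3 and DESeq2 1.26.0, with the mouse build mm10. Their roles and order, the gene annotation, the strand setting and any filter are not given in the sources used here. If strand was not used in counting, reads of a gene and of an overlapping gene on the other strand cannot be told apart. Reads of near-identical copies, as in the class II and immunoglobulin families, are uncertain for the same genes.

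In each library the low values were whole multiples of a single step, between 0.856 and 1.24 normalized counts per read. Division by that step gave values within 0.1 of a whole number for 100% of values in each library. Recovered reads totalled 56445754 and 68253936 in Etv3+/+ replicates 1 and 2, and 48278316, 42983550 and 59694413 in Etv3-/- replicates 1, 2 and 3. A group with 0 reads was given a floor of 3 reads over the group, 1.34 normalized counts for Etv3+/+ and 1.04 for Etv3-/-. Folds against such a group are lower bounds that cover counting error alone.

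Groups were taken from the genotype label. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Genes with a normalized count of 10 or more in at least 2 libraries were tested, 13813 in all. The test was limma 3.58.1 (lmFit, then eBayes with trend) in R 4.3.3 on log2(normalized count + 1) with genotype as the single term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale, which understates changes of low genes in general but can exceed the ratio of group means where 1 library of the lower group is at 0. With 2 against 3 libraries an exact permutation test has 10 splits and cannot give a p below 0.1. Intervals are at the 95% level.

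Of 33 gene lists fixed from general knowledge, 32 had at least 5 tested members and entered camera with a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry. With an estimated correlation, camera rests on the few residual degrees of freedom of 5 libraries. That version has little power here, whatever the correlation, so a list that does not pass it is not thereby refuted. The lists covered dendritic cell programmes, markers of other cell types and RNA quality. The named genes were Etv3, then the 12 highest and 12 lowest log2 fold changes among genes past the threshold. These had groups that did not overlap, a higher group mean of at least 50 and a curated symbol. Each list added up to 4 members past the threshold with the largest absolute change, or, where none passed, the 2 with the highest mean, given as values. Gene positions, GC content and transcript length came from GENCODE M21, on the same assembly as mm10, matched by symbol, with GC content and length for 98.5% of tested genes.

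The tests, lists, naming rule and most alternatives were set before the data were examined. The alternatives were other pseudocounts, filters and scalings, limma without trend, with robust or with sample weights, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the replicate number as a block, and each library left out. A correction for GC content and length by local regression with a span of 0.3, the omission of both libraries with the strongest GC trend, and edgeR with each library left out were chosen after seeing the data. The tests of technical explanations were also chosen after seeing the data. For the class II genes, a first pair of tests was replaced by a second pair after the first values had been seen. The class II list without Wdfy4, those ratios without it, and a test of macrophage RNA within each library were added later still, and all versions are reported. Figures were drawn with matplotlib 3.10.9.

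The procedure was tested on simulated data for Etv3-/- against Etv3+/+, with 13346 genes, 200 of them changed, in 5 runs. limma recovered 14.8% of genes changed by 2-fold, 69.2% by 4-fold, 83.6% by 8-fold and 90.8% by 16-fold, with 137 calls per run on average, 8 of them false. DESeq2 made 211 calls with 62.6 false, and edgeR 138 with 9.2 false. Without changes, limma called 0 genes and 0 lists in the 5 runs. Genes were simulated as independent, so this does not test false list calls where members are correlated. The estimated correlation was 0.85 for the ribosomal protein list and 0.80 for the mitochondrial list. With GC trends added to 13813 genes, uncorrected fits made 116 calls with 5.8 false, and corrected fits on 13609 genes made 129 with 7.8 false. Pairs of libraries of a genotype differed by far more than counting noise, with a chi-square per degree of freedom of at least 117, so none was counted as a repeat deposit of the same library. Repeat preparations of 1 sample would exceed counting noise too, so this does not show that the replicates were separate samples.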

Results

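Gene expression was compared between 2 Etv3+/+ and 3 Etv3-/- libraries of dendritic cells sorted from bone marrow cultured with GM-CSF and IL-4. Etv3 encodes a transcription factor of the ETS family, and the comparison addresses how its loss alters these cells. Recovered depth was 42983550 to 68253936 reads per library. The Pearson correlation of log2 values was 0.90 within Etv3+/+ and 0.90 to 0.92 within Etv3-/-, against 0.87 to 0.89 between genotypes. The first principal component held 36.5% of the variance and separated the genotypes.

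The targeted gene was examined first. Etv3 (chromosome 3, 87525407 to 87540156, GRCm38) had 23050 and 25447 normalized counts in the Etv3+/+ libraries and 18691, 20416 and 22856 in the Etv3-/- libraries. The log2 fold change was -0.23 (95% interval -0.70 to 0.23, limma adjusted p = 0.567). A two-sided exact permutation test over 10 splits gave p = 0.2, where 0.1 is the smallest possible. The sources used here do not say which part of the locus was disrupted, so a gene-level total does not check the knockout, and genotypes and all directions below are as labelled.

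Transcripts that were higher in Etv3-/- cells included H2-Ob, H2-Oa and H2-DMa of class II presentation, the complement genes C1qa, C1qb and C1qc, and the lectin receptor genes Mgl2 and Clec10a, and those of Fas, Il12b and Prdm1 were lower. Of 13813 genes tested, 121 rose and 44 fell (limma, adjusted p under 0.05). The median log2 fold change was 2.00 for genes that rose and -1.91 for genes that fell. For each of the 165 genes the values of the genotypes did not overlap. Among all tested genes 36.0% did not overlap, where chance gives 20%. At an unadjusted p under 0.05 there were 2480 genes. Without Etv3+/+ replicate 1 or 2 the count was 54 or 80, and without Etv3-/- replicate 1, 2 or 3 it was 0, 2 or 10, with 1885 genes at an unadjusted p under 0.05 and 0 edgeR calls where it was 0. No called gene changed sign in these omissions where it was still tested. That outcome was fixed in advance, because the groups of each called gene did not overlap, so it does not speak for stability. The calls themselves were less stable over 25 refits with other settings or fewer libraries (20 for Egfl6 and Ighg2b). Mgl2 lost its call in 5 of them, Fas in 7, H2-Ob in 8 and Clec10a in 10. Prdm1 lost it in 13, Il12b in 14, C1qb in 15 and Thsd1 in 18. The range over the named called genes was 5 to 18.

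**Figure D1:**
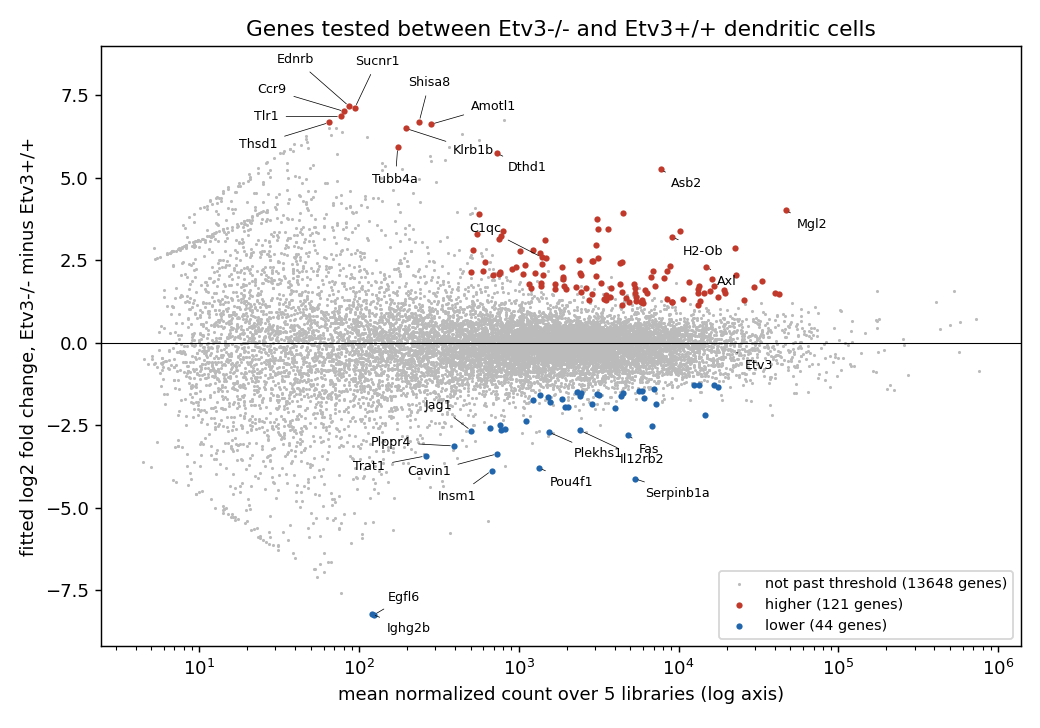
Each point is a tested gene, with its mean normalized count over the 5 libraries on a log axis and its fitted log2 fold change, Etv3-/- minus Etv3+/+; red marks the 121 genes that rose and blue the 44 that fell. Etv3 lies near 0 with a log2 fold change of -0.23, and genes at the far left and at the steep edges include those with 0 reads in a genotype, whose fitted change is not a bound.

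Among the 12 named genes with the largest rises, Mgl2 and Asb2 were the most abundant. Mgl2, a galactose-type C-type lectin receptor (chromosome 11, 70130329 to 70137550), rose 16.2-fold, from 4787 ± 1911 (SD, n = 2) to 74800 ± 7686 (SD, n = 3) normalized counts (limma adjusted p = 0.00467). Asb2, a subunit of a ubiquitin ligase, rose 38.2-fold, from 305 ± 121 to 12659 ± 6662. Low genes with 0 reads in both Etv3+/+ libraries rose as well. Ednrb, an endothelin receptor, was at least 108-fold higher, Sucnr1, the succinate receptor, at least 117-fold, Ccr9, a chemokine receptor, at least 101-fold, and Tlr1 at least 96.0-fold. Thsd1 was also at 0 in Etv3+/+ and at least 81.2-fold higher. Amotl1 rose 98.7-fold, Tubb4a 60.9-fold and Dthd1 53.6-fold, each from a mean of at most 19.7 normalized counts. Shisa8 and Klrb1b, at 0 in Etv3+/+ replicate 1, rose 104-fold and 90.4-fold on the fitted scale, and 61.1-fold and 58.3-fold by group means.

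The genes that fell most included Serpinb1a, a protease inhibitor, which fell 17.4-fold from 12175 ± 1773 to 744 ± 316 normalized counts. The transcription factor genes Insm1 and Pou4f1 fell 14.7-fold and 13.8-fold. Fas, the death receptor (chromosome 19, 34290666 to 34327772), fell 6.96-fold, from 9923 ± 1992 to 1419 ± 208 (limma adjusted p = 0.00765). Il12rb2, an IL-12 receptor chain, fell 6.30-fold and the Notch ligand gene Jag1 6.33-fold. Trat1 fell 10.8-fold, Cavin1 10.3-fold, Plppr4 8.74-fold and Plekhs1 6.53-fold. Egfl6 and the immunoglobulin gene Ighg2b had 0 reads in all 3 Etv3-/- libraries and were at least 296-fold and 289-fold lower. Of the 47 named genes that passed, 17 overlap another annotated gene, 14 of them on the opposite strand, such as Il12rb2 with Serbp1 and H2-DMa with Brd2, and their values are uncertain where strand was not used. Values of the neighbouring lectin genes Mgl2 and Clec10a are uncertain where reads map to both.

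Genes of MHC class II presentation rose as a group. Of 21 tested members 6 rose and 0 fell, or 11 and 1 adjusted over the list alone, with a median log2 fold change of 0.79 (limma camera adjusted p = 5.38e-09, or adjusted p = 0.329 with an estimated correlation). H2-Ob and H2-Oa, chains of a modulator of peptide loading, rose 9.27-fold and 3.57-fold, and H2-DMa, a chain of the loading catalyst, 3.70-fold. Wdfy4, which acts in cross-presentation on class I rather than in class II presentation, rose 15.3-fold. Without Wdfy4, an omission chosen after seeing the data, 5 of 20 members rose, with a median of 0.78 (camera adjusted p = 9.97e-08, or adjusted p = 0.329 with an estimated correlation). H2-Ob went from 1582 ± 639 (SD, n = 2) to 14123 ± 1665 (SD, n = 3) normalized counts. The 6 rises became 5 or 3 without Etv3+/+ replicate 1 or 2, and 0, 0 or 2 without Etv3-/- replicate 1, 2 or 3, while the list passed in each case. For class I presentation, 0 of 21 members passed (1 rise adjusted over the list alone; camera adjusted p = 0.0457, median 0.30, and adjusted p = 0.590 with an estimated correlation). The class I list lost its call in 15 of 25 refits, among them limma without any library other than Etv3-/- replicate 2 (adjusted p = 0.0553 to 0.137, with a median of 0.17 without Etv3-/- replicate 3) and a correction for GC content and length (adjusted p = 0.160, median 0.20). B2m was at 204222 and 160200 and H2-D1 at 358834 and 477549 mean normalized counts in Etv3+/+ and Etv3-/-.

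**Figure D2:**
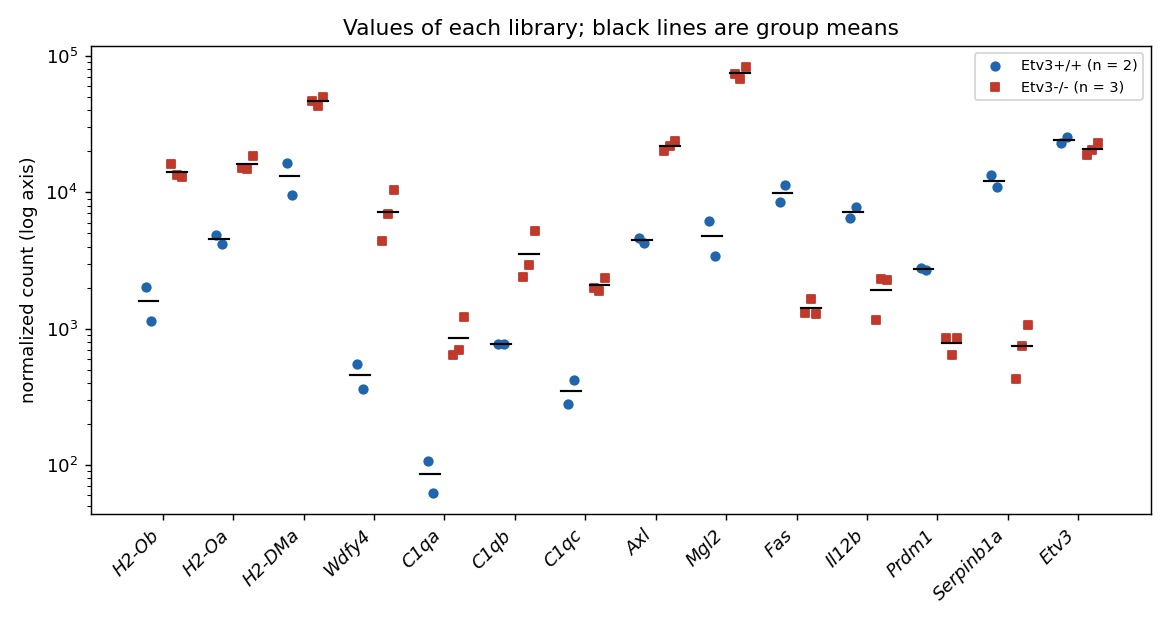
Normalized counts of named genes in each library on a log axis, with circles for the 2 Etv3+/+ and squares for the 3 Etv3-/- libraries, and black lines at group means. H2-Ob had 1130 and 2034 normalized counts in Etv3+/+ and 12877 to 16014 in Etv3-/-, while the Etv3 values of the genotypes lay close together.

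Some markers of other cell types were higher in Etv3-/- as well, though most were not called. On the macrophage and monocyte list 3 of 25 members rose, the complement genes C1qa by 9.83-fold, C1qb by 4.30-fold and C1qc by 6.05-fold, and 0 fell, with 10 rises adjusted over the list alone (camera adjusted p = 5.49e-05, or adjusted p = 0.329 with an estimated correlation). C1qc went from 348 ± 95.7 to 2082 ± 242 normalized counts. Without Etv3+/+ replicate 1 or 2 the number of rises on that list was 1 or 2, and without any of the 3 Etv3-/- replicates it was 0, while the list passed in each case. The B cell list passed with 0 of 14 members called (1 adjusted over the list alone; median 1.58, camera adjusted p = 0.0011, or adjusted p = 0.350 with an estimated correlation), and its median was 0.97 without Etv3+/+ replicate 1. Cd79b was at 418 ± 221 and 1413 ± 382 and Ighm at 1025 ± 309 and 1771 ± 430 normalized counts. On the cDC2 list, markers of conventional type 2 dendritic cells, 2 of 14 members rose, Mgl2 and the related lectin gene Clec10a by 13.6-fold (5 adjusted over the list alone; camera adjusted p = 0.0039, or adjusted p = 0.329 with an estimated correlation). On lists that did not pass, Wdfy4 and Naaa (3.33-fold) rose among 11 cDC1 genes, Ccr9 among 12 plasmacytoid genes and Ltc4s (3.90-fold) among 9 Langerhans-like genes. With edgeR without Etv3-/- replicate 1, the cDC1 and plasmacytoid lists passed upward (adjusted p = 0.0318 and 0.0349).

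Among signalling and response lists, IL-4 and STAT6 response genes passed upward, with 3 rises and 1 fall among 30 members (6 and 2 adjusted over the list alone; camera adjusted p = 0.0187, or adjusted p = 0.350 with an estimated correlation). Besides Mgl2 and Clec10a, Tgm2, a transglutaminase, rose 2.86-fold. Cd1d1, a lipid antigen presenter whose gene lies within 5 Mb of Etv3, fell 3.87-fold. Costimulatory and T cell contact genes passed upward with 2 rises and 1 fall among 23 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0207, or adjusted p = 0.329 with an estimated correlation). Cd70, a TNF family ligand, rose 4.21-fold and the integrin gene Itgal 5.38-fold, while Il12b, the p40 chain of IL-12, fell 3.91-fold from 7170 ± 988 to 1912 ± 654 normalized counts. Mature migratory dendritic cell genes passed downward with Il12b alone called among 39 (8 falls adjusted over the list alone; median -0.25, camera adjusted p = 0.0105, or adjusted p = 0.493 with an estimated correlation). That list did not pass without Etv3-/- replicate 1 (adjusted p = 0.0736), and the IL-4 and the costimulatory lists did not pass without Etv3+/+ replicate 1 (adjusted p = 0.114 for both), nor the IL-4 list with the GC and length correction (adjusted p = 0.0541). The mature list's median was -0.14 with edgeR without Etv3-/- replicate 2. GM-CSF and STAT5 response genes passed downward with 0 of 26 called (1 rise and 2 falls adjusted over the list alone; median -0.47, camera adjusted p = 0.0242, or adjusted p = 0.329 with an estimated correlation), where Jak2 was at 155343 and 96066 and Id2 at 120152 and 85424 mean normalized counts. The GM-CSF list did not pass without Etv3+/+ replicate 1 (adjusted p = 0.0569) or Etv3-/- replicate 2 (adjusted p = 0.0855), nor in limma with trend=FALSE (adjusted p = 0.0590). Its median was -0.20 without Etv3+/+ replicate 2, or -0.13 with edgeR, and -0.30 with edgeR without Etv3-/- replicate 3.

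On the immunoregulatory list Fas was the single called gene among 39, and the list did not pass (camera adjusted p = 0.616). Prdm1, which encodes the repressor BLIMP-1, fell 3.50-fold among 35 dendritic cell transcription factor and receptor genes (camera adjusted p = 0.233). Cdkn1b, a cell cycle inhibitor gene, fell 5.57-fold among 47 cell cycle genes (camera adjusted p = 0.469). On the NF-kB list Tnfaip2 rose 3.03-fold and Ikbke 2.52-fold among 28 (camera adjusted p = 0.170). On the inflammatory list the chemokine gene Ccl2 rose 7.08-fold and Il12b fell among 33 (camera adjusted p = 0.484). The phagocytic receptor gene Axl rose 4.95-fold on the lysosome and uptake list, 1 of 33 (camera adjusted p = 0.0242, or adjusted p = 0.350 with an estimated correlation). The chaperone gene Hyou1 rose 3.46-fold on the unfolded protein response list, 1 of 24 (camera adjusted p = 0.0251, or adjusted p = 0.350 with an estimated correlation). Adjusted over the list alone, rises and falls numbered 5 and 3 (immunoregulatory), 3 and 2 (transcription factor and receptor) and 2 and 3 (cell cycle). They numbered 5 and 1 (NF-kB), 2 and 5 (inflammatory), 7 and 0 (uptake) and 1 and 0 (unfolded protein). The uptake list did not pass without Etv3+/+ replicate 1 (adjusted p = 0.0924) or Etv3-/- replicate 1 (0.0630), nor in limma with trend=FALSE (0.0645). The unfolded protein list did not pass without Etv3+/+ replicate 2 (0.131) or Etv3-/- replicate 1 (0.0621), nor with edgeR without Etv3+/+ replicate 1 (0.0719).

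**Figure D3:**
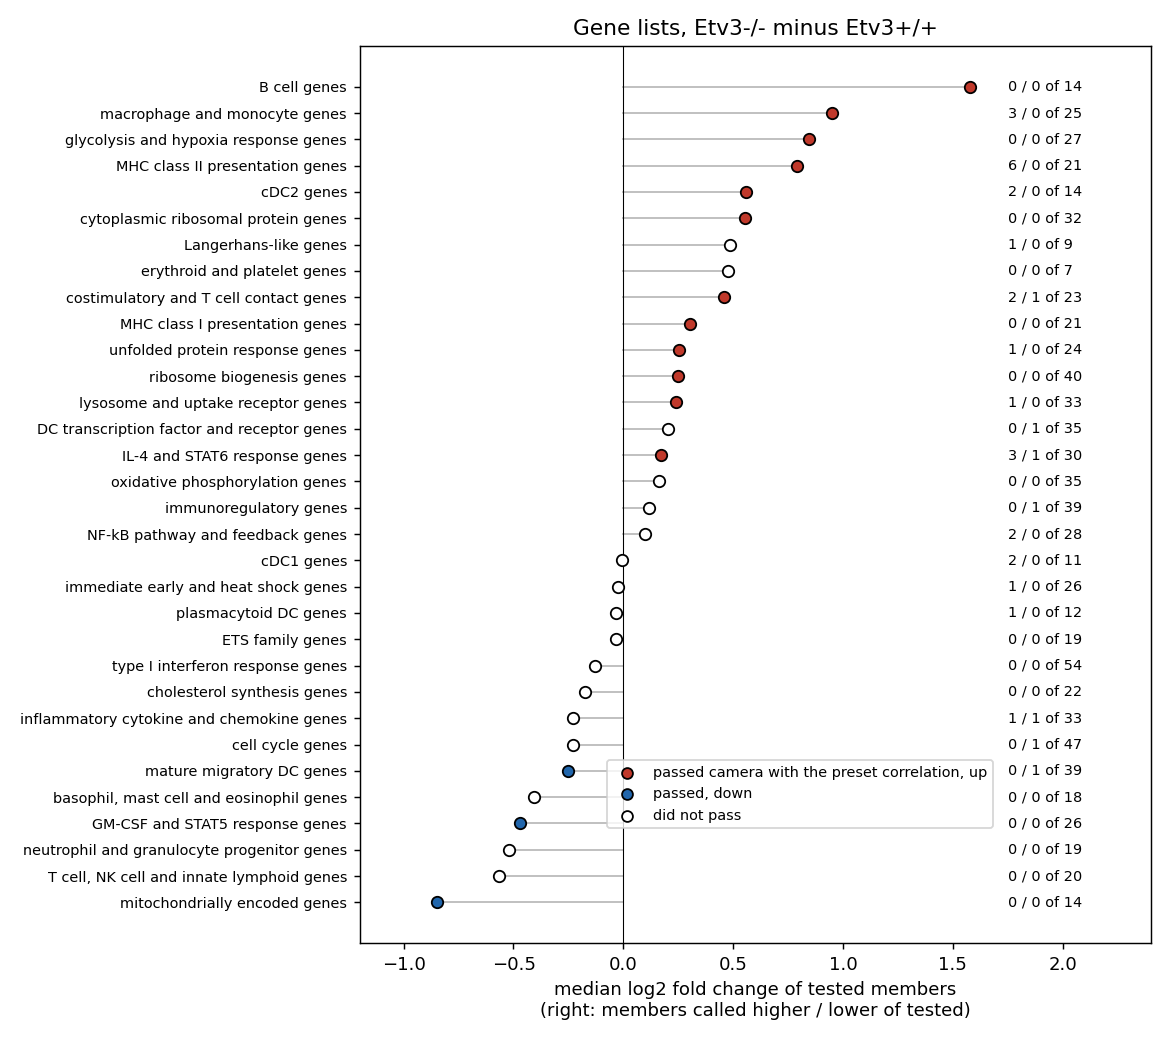
Median log2 fold change of the tested members of each of 32 gene lists, Etv3-/- minus Etv3+/+, with filled circles for lists that passed camera with the preset correlation and the numbers of called members at the right. The class II list had 6 of 21 members called higher. With an estimated correlation, a version with little power at 5 libraries, 0 of the 32 lists passed.

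In all, 12 lists passed upward and 3 downward with the preset correlation, 0 with an estimated correlation (lowest adjusted p = 0.329), 3 with fry in one direction and 21 with fry in either direction. Those passing fry in one direction were class II (fry adjusted p = 0.0288), cDC2 (0.0288) and GM-CSF (0.0347) genes. The estimated correlation was -0.025 for cDC2, -0.019 for costimulatory and -0.021 for GM-CSF genes, below the preset 0.01. For these lists the lost call thus reflects the few degrees of freedom, not correlation between genes. Measures of RNA quality differed between libraries. Mitochondrial genes took 1.98% and 6.64% of normalized counts in Etv3+/+ replicates 1 and 2, and 2.31%, 3.17% and 1.10% in Etv3-/- replicates 1, 2 and 3. Their list passed downward with 0 of 14 called (camera adjusted p = 0.0387, or adjusted p = 0.659 with an estimated correlation), and its median of -0.85 became 0.24 without Etv3+/+ replicate 2 and -2.12 without Etv3+/+ replicate 1. With the GC and length correction the median was -0.07 (adjusted p = 0.449), and the list also did not pass without Etv3-/- replicate 1 (adjusted p = 0.0685) or 3 (adjusted p = 0.211), with trend=FALSE (adjusted p = 0.0871) or with sample weights (adjusted p = 0.0525). It passed upward without both libraries with the strongest GC trend (median 0.63, adjusted p = 0.00115). The Spearman correlation of a library's deviations with GC content, across genes, was -0.42 in Etv3+/+ replicate 2 and 0.41 in Etv3-/- replicate 3. The ribosomal protein list passed upward with 0 of 32 called (median 0.55, camera adjusted p = 5.38e-09, or adjusted p = 0.590 with an estimated correlation), with a median of 0.36 without Etv3+/+ replicate 1 and of 0.84 with edgeR without Etv3+/+ replicate 2. On the immediate early list Fos rose 3.47-fold, 1 of 26 (camera adjusted p = 0.484), with 2 rises and 1 fall adjusted over the list alone.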

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

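The GC and length correction, the omission of both libraries with the strongest GC trend, edgeR without each library in turn and the class II list without Wdfy4 were chosen after seeing the data. No called gene changed sign in 25 refits, yet each named one lost its call in 5 to 18. The 121 genes higher and 44 lower stayed within 1.5 times under a pseudocount of 0.5, both filters, TMM and quantile scaling, robust limma, sample weights and edgeR on recovered reads (114 and 44, 151 of them shared). With a pseudocount of 5, 70 genes were lower. limma with trend=FALSE called 44 higher and 49 lower, 19 of them shared with the 165. DESeq2 called 644 and 544, including the 165, and made 62.6 false calls among 211 in simulation. Across the single-library omissions, limma called 0 to 73 higher and 0 to 7 lower, and edgeR 0 to 7 and 0 to 3. These fits have fewer samples, and the omission of an Etv3+/+ library leaves 1, which is assumed to vary like the others. limma without Etv3-/- replicate 1 called 0 with 1885 genes at an unadjusted p under 0.05. edgeR called 0 without each Etv3+/+ library (2305 and 1707 at an unadjusted p under 0.05) and without Etv3-/- replicate 1 or 2 (1780 and 2193). The GC and length correction gave 236 and 91, and 43 and 17 with the replicate block. Without both libraries of strongest GC trend there were 6 and 1. The replicate block gave 151 and 118. Number 3 occurs in Etv3-/- alone, so with the block Etv3-/- replicate 3 does not enter the genotype difference. That difference then rests on replicates 1 and 2 of each genotype. The neutrophil list, which passed downward with the block, also did so without Etv3-/- replicate 3. Same-numbered libraries had deviation correlations of -0.03 and 0.04. The deviations of the 2 Etv3+/+ libraries mirror each other, so both values rest on 1 contrast. They cannot tell whether a shared number pairs libraries. With the block, the class I list did not pass (adjusted p = 0.128), while the interferon list (1 gene higher and 5 lower, adjusted p = 0.0256) and the neutrophil list (0 and 3, adjusted p = 0.000695) passed downward. With the block and the GC and length correction, the class I (adjusted p = 0.284), IL-4 (0.124) and mitochondrial (0.567, median -0.18) lists did not pass, while the interferon (0.0197) and neutrophil (0.00127) lists did. Of 15 lists passing, 0 passed with an estimated correlation and 3 with fry, and 10 to 16 lists passed in the 25 refits (13 with the GC and length correction, 11 with trend=FALSE). The correction ended the calls of the IL-4 (adjusted p = 0.0541), class I (0.160) and mitochondrial lists, trend=FALSE those of the class I (0.0871), GM-CSF (0.0590), uptake (0.0645) and mitochondrial (0.0871) lists, and the omission of both libraries with the strongest GC trend those of the class I (0.224) and unfolded protein (0.112) lists. The mitochondrial list, with a median of -0.85, ranged from -2.12 without Etv3+/+ replicate 1 to 0.24 without replicate 2 (0.45 with edgeR), and was 0.63 without both libraries of strongest GC trend. The GC and length correction ended its call because the median moved close to 0, from -0.85 (quartiles -0.98 and -0.77) to -0.07 (quartiles -0.38 and 0.02). The class II list passed in all 25 refits. Except for fewer samples, and the GC and length trend in the mitochondrial list, the cause of these shifts was not tested. At this depth and n, limma recovered 14.8% of simulated 2-fold changes, so changes of that size are mostly below reach.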

Other observations

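Glycolysis and hypoxia response genes passed upward with 0 of 27 called (10 adjusted over the list alone; median log2 fold change 0.85, limma camera adjusted p = 1.69e-07, or adjusted p = 0.544 with an estimated correlation of 0.55), and its median was 0.55 with edgeR without Etv3-/- replicate 1. Aldoa, a glycolytic aldolase gene, was at 63288 and 131158 and Ldha, for lactate dehydrogenase, at 48195 and 92159 mean normalized counts in Etv3+/+ and Etv3-/-. Ribosome biogenesis genes passed upward with 0 of 40 called (3 adjusted over the list alone; camera adjusted p = 8.00e-04, or adjusted p = 0.329 with an estimated correlation). The most abundant members lay on the other side of 0, with Ncl at a log2 fold change of -0.19 and Npm1 at -0.27. Oxidative phosphorylation genes had 0 of 35 called (camera adjusted p = 0.137), with Atp5a1 at 0.18 and Atp5b at 0.33. Cholesterol synthesis genes had 0 of 22 called (camera adjusted p = 0.662), with Cyp51 at 0.71 and Srebf2 at 0.02.

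Type I interferon response genes had 0 of 54 called (2 and 6 adjusted over the list alone; camera adjusted p = 0.616), with Irf1 at a log2 fold change of 0.40 and Samhd1 at -0.71. ETS family genes had 0 of 19 called (camera adjusted p = 0.806), with Etv6 at -0.22. Neutrophil genes had 0 of 19 (camera adjusted p = 0.616), with S100a8 at -1.17 and S100a9 at -0.60, and basophil, mast cell and eosinophil genes 0 of 18, with no call by camera, and with Prss34 at 0.25 and Kit at -0.11. T cell, NK cell and innate lymphoid genes had 0 of 20 (camera adjusted p = 0.0994), with Il7r at -1.27 and Gzma at -2.70. That list passed downward without Etv3-/- replicate 1 (adjusted p = 0.0112) or 2 (adjusted p = 0.0324) and with the GC and length correction (adjusted p = 0.0435). The neutrophil list passed downward without Etv3-/- replicate 3 (adjusted p = 0.00394) and without both libraries with the strongest GC trend (adjusted p = 2.98e-05). Erythroid and platelet genes had 0 of 7 (camera adjusted p = 0.616), or 1 fall adjusted over the list alone, with Car2 at -0.13 and Pf4 at 0.58. The stromal and endothelial list had 4 tested members and entered no set test, with Acta2 at -1.10 and Pecam1 at 0.22. Within 5 Mb of Etv3, 2 of 122 genes were called (Cd1d1 and Il6ra, the latter named after its value was seen), against 161 of 13462 elsewhere (two-sided Fisher's exact p = 0.659). This pooled count cannot tell whether the change of a single neighbour, such as Cd1d1 (chromosome 3, 86995834 to 86999441), comes from its place near the altered locus.

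All tests of explanations in the following paragraphs were chosen after the results were seen. The first pattern is the 165 called genes. Fold changes correlated with GC content across genes (Spearman 0.29, 0.00 after the correction), yet 158 of the 164 called genes with a GC value kept their call and sign, and their median absolute log2 fold change went from 1.97 to 1.88. This argues against the GC and length trend as the whole cause. Of the 10 splits of the 5 libraries into 2 and 3, 1 gave as many calls, the real one with 165, and the highest other gave 0 in limma (169 to 1564 genes at an unadjusted p under 0.05), which is too few splits for a share under 0.05. Genotype, with any difference between cultures that goes with it, stays open.

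The second pattern is the rise of C1q and class II genes, for which RNA from macrophages or B cells was weighed. Yet the sort gate, positive for CD11c, intermediate for CD11b and negative for CD115, would remove B cells and CD115-positive macrophages. The gate also took cells high for MHC class II in both genotypes, and how that choice bears on the class II rise was not tested. For C1q, macrophage RNA stays a candidate explanation: the other 22 macrophage and monocyte genes had a median log2 fold change of 0.73, with 14 above 0 and 8 below (camera p = 0.0011, or p = 0.0444 with an estimated correlation), and of the most abundant, Ctsb was at 0.24, Gpnmb at -0.25 and Lyz2 at 0.66. For the 6 called class II genes, macrophage RNA was tested in 3 versions, each later one chosen after the values before it were seen: their median against that of those 22 genes (difference 1.13, SE of the list's median 0.39), the largest summed gain of the macrophage list over the smallest summed gain of the class II genes, from any libraries (0.961, or 0.0681 to 0.961 when a library was left out, and 1.03 without the cross-presentation gene Wdfy4, or 0.0733 without Etv3-/- replicate 1, 0.827 without Etv3+/+ replicate 1 and 0.935 without Etv3-/- replicate 2), and both gains within the same library, without Wdfy4 and with list members that fell counted as 0 (at most 0.965, 0.316 and 0.472 in Etv3-/- replicates 1, 2 and 3). In the first version the SE came from 2000 bootstrap draws for the list's median alone, and it does not cover the called genes. Those 6 genes were picked for rising and the 22 were not, which widens the difference. With falls counted in full, the third version gave 0.924 and 0.762 in Etv3-/- replicate 1, against Etv3+/+ replicates 1 and 2. It gave -0.150 and -0.111 in Etv3-/- replicate 2, and 0.053 and 0.052 in replicate 3. The summed macrophage list was at 193419 and 192450 normalized counts in Etv3+/+, and at 279464, 180800 and 198618 in Etv3-/- replicates 1, 2 and 3. It thus rose in replicate 1 and changed little in replicates 2 and 3. The C1q genes did not follow this sum, and each was highest in Etv3-/- replicate 3. In Etv3-/- replicates 1, 2 and 3, C1qa was at 636, 692 and 1224 normalized counts. C1qb was at 2409, 2946 and 5234, and C1qc at 1995, 1895 and 2355. For B cell RNA the ratio was 0.526 against H2-Ob alone in a first version, and 0.0630 against the 6 genes (0.0679 without Wdfy4) in a second. No library of macrophages or B cells was analysed here, so how many counts their RNA holds on these lists for each count of the class II genes is not known, and RNA from either stays open for the class II rise, as does an effect of genotype.

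The third pattern is the fall of 44 genes, among them Il12b and Fas. The test assumed that fewer mature migratory dendritic cells in the sort would lower the whole list of their genes by about as much. The 39 listed genes had a median log2 fold change of -0.25 (interquartile range 0.84) against -1.91 for the genes that fell, a difference of 1.65, or 1.06 from the median upper bound of the 95% intervals of those genes. The genes that fell were picked for falling and the listed genes were not, which widens both differences. Listed genes that other sorted cells express too would also fall less. The differences therefore cannot decide on a lower share of such cells. Of the 39, 28 were below 0 and 11 above, and 8 fell adjusted over the list alone, so a lower share of such cells may contribute. RNA of cells outside the sort gate was not tested for the falls. The T cell, NK cell and innate lymphoid list summed to 52619 mean normalized counts in Etv3+/+ and 21979 in Etv3-/-. Of its 20 tested members 14 were below 0 and 6 above, with 0 called (median -0.57, camera adjusted p = 0.0994). A change within a subset of the cells, or an effect of genotype, may still contribute.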
